A study of Homo sapiens with 8 samples.

How the data were processed

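Reduced representation bisulfite sequencing (RRBS), which sequences a CpG-rich part of the genome after bisulfite conversion, was analysed in 8 libraries from HUES64 human embryonic stem cells. Per the labels, the cells carry knockouts of DNMT3A and DNMT3B, and the libraries come from passages 6, 7, 8, 11, 13, 17, 27 and 28, with 1 library at each. No library of unedited cells was analysed here. The labels do not say whether the passages are successive samples of 1 culture or clone, so p-values measure only the spread of these libraries around a trend, which may be technical.

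Each deposited file lists CpG positions of genome build hg19, per the submitters' processing notes. The deposited methylated and total reads of each CpG were taken from the fourth column. The deposited score in the fifth column is 1000 times the methylated share of those reads, rounded to a whole number, as checked on every line, and was not used further. The aligner, the methylation caller, any filter on coverage and any removal of duplicate reads are not given in the sources used here. Duplicate reads would make counting intervals too narrow. Positions are printed counted from 1.

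The files held between 2793772 CpGs at passage 11 and 2913127 at passage 6. Summed over CpGs, reads numbered 44599588 at passage 6, 24156907 at passage 7, 20219105 at passage 8 and 19898423 at passage 11. The later libraries had 23087958 reads at passage 13, 22630871 at passage 17, 26385289 at passage 27 and 28917356 at passage 28. Median coverage per listed CpG was 13 at passage 6 and between 6 and 8 in the other libraries. Autosomal CpGs with at least 10 reads in every library were kept, which left 203892 CpGs. Their median coverage was 34 at passage 6 and between 16 and 22 elsewhere. Chromosome X was kept apart, and chromosome Y was not used.

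The mean methylation level of a library gave each CpG the same weight. Trends were fitted by least squares on the passage number, and the p of a slope is that of Pearson's r, by a two-sided exact permutation test over all 40320 orders of the 8 libraries. The smallest p these orders allow is 2.5e-05 for r and 5e-05 for Spearman's rho, and over the 720 orders of 6 libraries it is 0.00139 for r. The 26 trends computed form 1 family for Benjamini-Hochberg adjustment, and the 5 differences of slopes form another. Libraries of neighbouring passages differed by more than read counting alone would give, with a mean chi-square per CpG of at least 1.65. Duplicate reads or differences between library preparations could also give this. No library was treated as a duplicate of another.

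Reads were summed over tiles of 1000 bases with at least 3 of the kept CpGs, giving 22626 tiles. Each tile was fitted by quasi-binomial logistic regression of methylated and unmethylated reads on passage, with the dispersion moderated by limma's squeezeVar, a two-sided F test and Benjamini-Hochberg adjustment. A tile was called at an adjusted p under 0.05 with a fitted change of at least 10 percentage points between passages 6 and 28. A tile was tested only with 10 methylated and 10 unmethylated reads over all libraries, and the dispersion was not allowed under 1, the binomial value. These last 2 settings were not part of the design fixed beforehand. They were added after a fit without them gave too many small p-values on simulated unchanged tiles, 12.4% of which had a p under 0.05, against 5.01% with them. In simulated data for this fit, run on 11784 tested tiles, 98% of tiles falling by 40 points and 100% of those rising by 40 points were recovered. For changes of 20 points the shares were 36% of falls and 34% of rises. There were 8 calls among unchanged tiles. The changed tiles were drawn only from tiles of intermediate mean level. Every simulated tile was given the same dispersion, the median of the tested tiles. These shares therefore do not cover tiles of high or low level or of larger dispersion.

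CpG density was the number of CpG positions listed in any of the files per tile, and the starting level was the mean over passages 6 to 8. Named tiles were fixed by rule as the 5 called tiles with the largest fall between the mean of passages 6 to 8 and the mean of passages 27 and 28, the 5 with the largest rise, and the 5 with the highest mean at passages 27 and 28 among tiles of at least 5 CpGs that started at 80% or more. No annotation of hg19 was used here, so tiles carry no gene names. For that reason the planned promoters, gene lists, imprinted regions, promoter, gene body and intergenic classes, and the housekeeping promoters meant as a background for conversion were not analysed here. Chromosome M was not analysed here either, and tiles under 1% on average over all libraries served as the conversion floor.

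Alternatives fixed before the data were examined were coverage minimums of 5 and 20 reads, chromosome X, omission of each library, pooled reads, per-library CpG sets, an upper coverage limit, a log2 passage scale, other class and level bounds, limma on logit levels, early against late passages, other minimum changes, other tiles, and reads thinned to equal coverage for the tiles. Those added later were passages 6 to 17 only, thinned reads for the library means, no minimum of reads of each state, no floor on the dispersion, tiles starting at 80% or more, tiles starting at 60% or more at a minimum of 5 reads, and a start classed on passage 6 alone. Intervals are 95% Wilson intervals and cover counting error only. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and data.table version 1.17.8 were used.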

Results

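HUES64 is an established human embryonic stem cell line. The libraries analysed here came from HUES64 cells lacking DNMT3A and DNMT3B, the enzymes that set methylation on unmethylated DNA, while DNMT1, which copies methylation to the new strand after replication, was not among the disrupted genes named for them. CpG methylation was measured by RRBS at passages 6, 7, 8, 11, 13, 17, 27 and 28, with 1 library per passage and no replicate library at any of them. The design asks how methylation changed while the cells were kept in culture without both enzymes. Reads over CpGs ranged from 19898423 at passage 11 to 44599588 at passage 6.

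Methylation fell steadily with passage. The mean level over 203892 autosomal CpGs was 41.4% at passage 6, 41.2% at passage 7, 40.8% at passage 8, 38.8% at passage 11, 38.6% at passage 13, 36.9% at passage 17, 32.3% at passage 27 and 31.3% at passage 28. From a mean of 41.1% ± 0.311 (SD, n = 3) over passages 6 to 8 to a mean of 31.8% over passages 27 and 28, it fell by 9.34 percentage points. The slope was -0.451 ± 0.0133 points per passage (SE, n = 8), with r = -0.997 (exact permutation p = 2.5e-05, adjusted p = 4.3e-05) and rho = -1 (exact permutation p = 5e-05), the smallest p values that 8 libraries allow. Without passages 27 and 28, the farthest from the median passage, r was -0.989 (exact permutation p = 0.00139, n = 6) and the slope -0.423 points per passage. Between passages 8 and 17 the mean changed by -0.427 points per passage and between passages 17 and 27 by -0.468. The adjacent libraries of passages 27 and 28 differed by -0.940 points and those of passages 6 and 7 by -0.134, so single steps cannot be ranked.

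**Figure D1:**
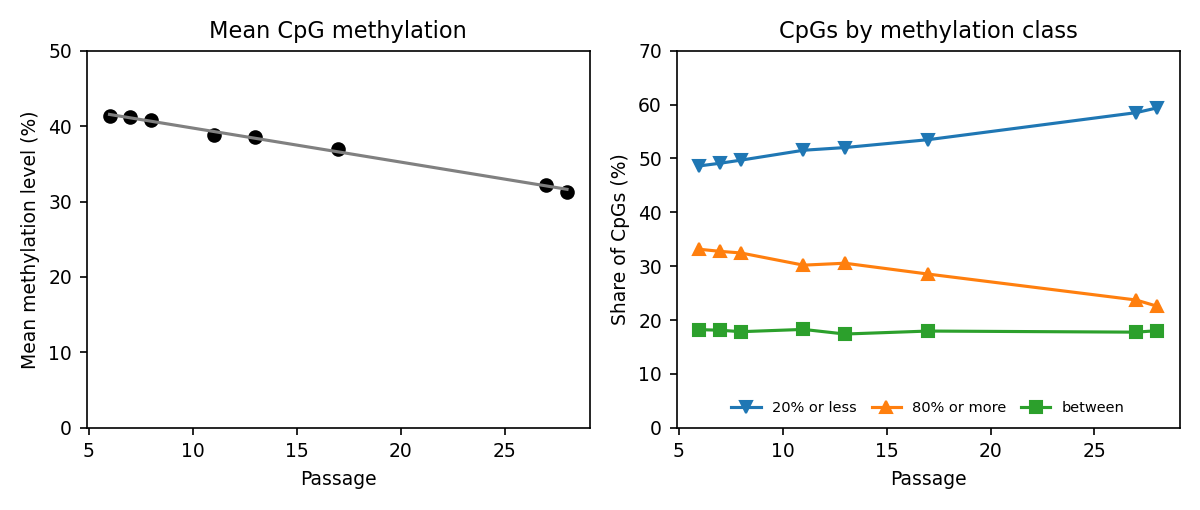
Mean methylation level of 203892 autosomal CpGs in percent (left, points, with the least-squares line) and share of CpGs in each methylation class in percent (right) against passage number, with 1 library per point. The mean fell from 41.4% at passage 6 to 31.3% at passage 28, while CpGs at 20% or less rose and CpGs at 80% or more fell.

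The share of highly methylated CpGs fell while that of weakly methylated CpGs rose. Single CpGs were not followed between these classes. Of the 4302 tiles that started at 80% or more, 2463 were still there at passages 27 and 28. Another 1752 lay between 20 and 80%, and 87 lay under 20%. Of the 1319 tiles that started between 40 and 60%, 779 ended under 20%. CpGs at 80% or more made up 33.1% of the total at passage 6 and 22.6% at passage 28, with a slope of -0.465 ± 0.0201 points per passage (SE, n = 8; r = -0.994, exact permutation p = 9.9e-05; rho = -0.976, exact permutation p = 0.0004). CpGs at 20% or less made up 48.6% at passage 6 and 59.4% at passage 28, with a slope of 0.473 ± 0.0123 (SE, n = 8; r = 0.998, exact permutation p = 2.5e-05). The share between these levels was 18.2% at passage 6 and 18.0% at passage 28, and its slope of -0.00848 ± 0.0127 (SE, n = 8) did not pass the test (exact permutation p = 0.536). That last result depends on the coverage minimum, since the intermediate share rose by 0.0627 points per passage at 5 reads (exact permutation p = 0.0205, n = 8) and by 0.0779 at 20 reads (exact permutation p = 0.0053, n = 8).

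Loss was spread over a large part of the tested genome. Of 11743 tested tiles of 1000 bases, 5589 (47.6%) lost methylation with passage and 21 gained it. Lost tiles changed by a median of -29.4 points (interquartile range -42.5 to -18.8), and 848 of them fell by 50 points or more. Gains had a median of 13.5 points. The share of tested tiles with a loss depended on the settings, at 33.9% with a minimum of 5 reads, 22.97% with a minimum of 20 reads and 18.8% over passages 6 to 17 alone. It was 20.6% with limma on logit levels (4651 of 22626 tested tiles). Under the design as first fixed, without the added limits on reads and dispersion, it was 28.9% (5167 of 17888). Both fits tested more tiles than the main fit, near-unmethylated ones included, so their shares do not have the same base as 47.6%.

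The tiles with the largest falls went from nearly full to nearly absent methylation. On chromosome 6 the tile at 168613001 to 168614000 (hg19, 5 CpGs) had 92.2% ± 2.89 (SD, n = 3) at passages 6 to 8 and a mean of 4.27% at passages 27 and 28, where its 306 pooled reads gave an interval of 2.50 to 7.13%. The tile on chromosome 3 at 47459001 to 47460000 (3 CpGs) went from 90.1% ± 3.84 (SD, n = 3) to 2.12%, and the tile on chromosome 21 at 44841001 to 44842000 (3 CpGs) from 92.1% ± 3.05 (SD, n = 3) to 4.81%. On chromosome 4 the tile at 3412001 to 3413000 (3 CpGs) went from 91.3% ± 4.37 (SD, n = 3) to 4.72%. On chromosome 19 the tile at 58868001 to 58869000 (3 CpGs) went from 93.1% ± 4.26 (SD, n = 3) to 7.78%. At passage 17 these tiles still stood at 81.0%, 74.4%, 85.7%, 84.7% and 93.9%, in the same order. Over passages 6 to 17 alone, the tiles on chromosomes 21, 4 and 19 no longer passed the test, with fitted changes of -4.05, -6.95 and -2.71 points and adjusted p of 0.717, 0.537 and 0.848 from the fit with limma's moderated dispersion.

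The largest rise was on chromosome 4 at 8966001 to 8967000 (5 CpGs), from 10.9% ± 12.7 (SD, n = 3) to 44.5%, with 58.1% at passage 27 and 31.0% at passage 28. The tile on chromosome 17 at 42733001 to 42734000 (5 CpGs) rose from 55.8% ± 4.23 (SD, n = 3) to 81.7%. On chromosome 1 the tile at 3052001 to 3053000 (4 CpGs) rose from 13.3% ± 6.02 (SD, n = 3) to 38.5%, and on chromosome 16 the tile at 867001 to 868000 (3 CpGs) from 12.3% ± 3.27 (SD, n = 3) to 34.2%. The tile on chromosome 7 at 712001 to 713000 (3 CpGs) went from 68.1% ± 9.92 (SD, n = 3) to 89.2%. Calls of 3 of these rises rest on few libraries: the chromosome 4 tile lost its call without passage 27 (fitted change 17.1 points, adjusted p = 0.172 with limma's moderated dispersion), the chromosome 16 tile without passage 27 (14.8 points, adjusted p = 0.155) or 28 (17.4 points, adjusted p = 0.145), and the chromosome 7 tile (adjusted p = 0.0481) on omission of any single library, with adjusted p between 0.0508 and 0.160. The same 3 also lost their calls without the added minimum of reads of each state, with adjusted p of 0.116, 0.0976 and 0.0615. At a minimum of 5 reads the chromosome 7 tile changed by 0.397 points (adjusted p = 0.968, moderated dispersion), while the chromosome 4 and 16 tiles kept their calls. With limma on logit levels the chromosome 4 and 16 tiles did not pass (adjusted p of 0.212 and 0.162), while the chromosome 7 tile did (0.0276).

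**Figure D2:**
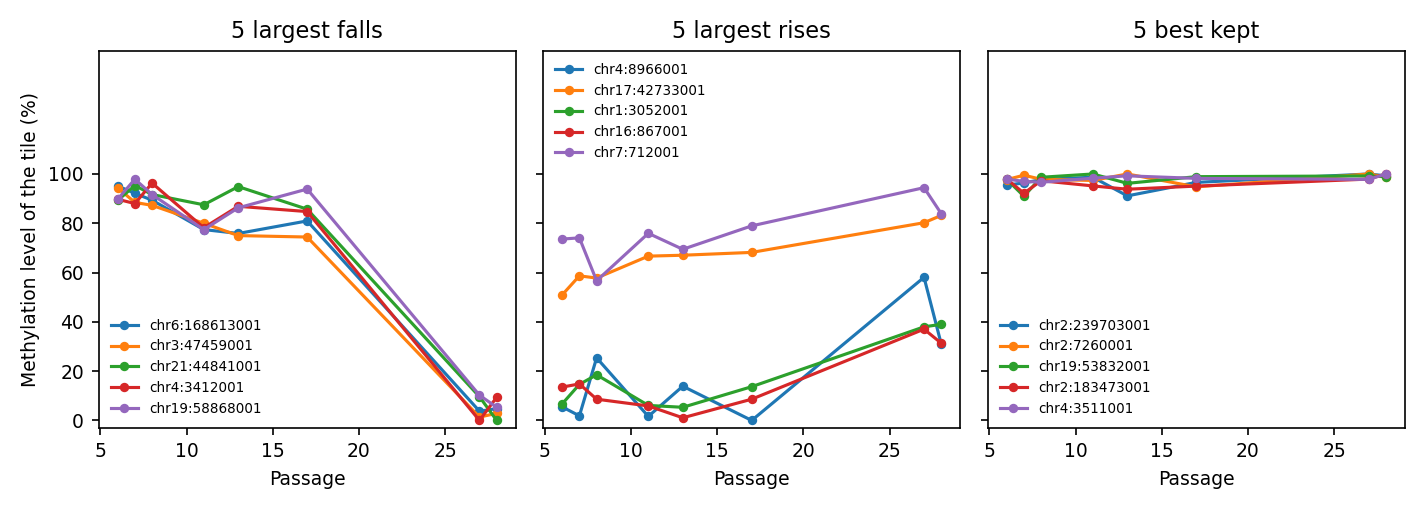
Methylation level in percent against passage number for the 5 tiles with the largest falls (left), the 5 with the largest rises (middle) and the 5 best kept (right), each named by chromosome and start in hg19, with 1 library per point. The 5 falling tiles lay at 74.4% or higher at passage 17 and at 10.2% or lower at passages 27 and 28.

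The share of methylation that tiles kept differed between starting levels. The 1319 tiles that started between 40 and 60% went from 49.96% ± 1.51 (SD, n = 3) to 19.9%, retaining 39.9% of the early level, and 978 of them were called as losses. The 1383 tiles that started between 20 and 40% went from 29.7% ± 1.12 (SD, n = 3) to 10.5%, retaining 35.3%. Tiles starting between 10 and 20% (938) retained 34.4%, going from 14.8% ± 1.11 (SD, n = 3) to 5.10%. The 12478 tiles that started under 10% retained 49.0%, going from 0.784% ± 0.0600 (SD, n = 3) to 0.384%. Retention thus did not rise with starting level throughout. Tiles starting between 60 and 80% (2206) retained 58.3%, going from 71.2% ± 0.885 (SD, n = 3) to 41.5%, and those between 80 and 90% (1827) retained 75.8%, going from 85.3% ± 0.320 (SD, n = 3) to 64.7%. The 2475 tiles that started at 90% or more went from 94.2% ± 0.228 (SD, n = 3) to 86.3% and retained 91.6%, with losses called in 577 of the 2449 tested. All 7 starting classes fell with passage (adjusted p at most 0.000269, exact permutation tests, n = 8). No difference between these classes was itself tested.

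**Figure D3:**
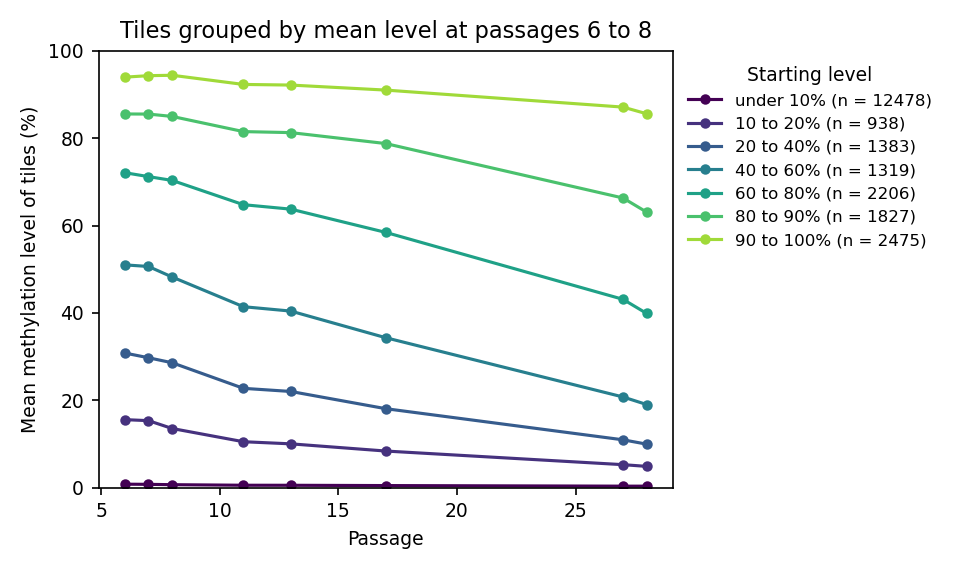
Mean methylation level in percent of tiles grouped by their mean level at passages 6 to 8, against passage number, with 1 library per point and the number of tiles in each group in the legend. Tiles starting at 40 to 60% fell to 19.9% at passages 27 and 28, while tiles starting at 90 to 100% stayed at 86.3%.

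Tiles with few CpGs had higher methylation levels and lost more points than CpG-dense tiles. Tiles with 3 to 9 listed CpGs went from 52.1% ± 0.441 (SD, n = 3) to 38.4%, those with 10 to 19 from 39.1% ± 0.508 (SD, n = 3) to 26.0%, those with 20 to 34 from 20.5% ± 0.242 (SD, n = 3) to 13.5%, and those with 35 or more from 7.15% ± 0.0709 (SD, n = 3) to 5.37%. The slope of the densest tiles minus that of the sparsest was 0.571 ± 0.0199 points per passage (SE, n = 8; exact permutation p = 2.5e-05, adjusted p = 0.000124). Among tiles that started at 60% or more the densest went from 84.5% to 68.0% and the sparsest from 83.9% to 67.5%, and the difference of slopes was -0.00818 ± 0.0409 (SE, n = 8; exact permutation p = 0.840). At a minimum of 5 reads that difference was 0.114 ± 0.0260 (SE, n = 8; exact permutation p = 0.00499), so dense tiles of high start lost less at that setting. At 10 reads the middle classes starting at 60% or more fell farther, from 83.7% to 62.5% (10 to 19 listed CpGs) and from 84.3% to 62.8% (20 to 34), which was not tested. At a start of 80% or more, the slope with 20 to 34 minus that with 3 to 9 was -0.0848 ± 0.0272 (SE, n = 8, exact permutation p = 0.0286, adjusted p = 0.0477). Its rho was -0.310 (exact permutation p = 0.462).

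At a level of 80%, a majority of highly methylated tiles stayed highly methylated. Of 3591 tiles at 80% or more in each of passages 6, 7 and 8, 2108 were still at 80% or more in both passages 27 and 28, a share of 58.7% (Wilson interval 57.1 to 60.3%). At a level of 90% it was no majority, with 798 of 1645 tiles kept (48.5%, Wilson interval 46.1 to 50.9%). The best kept tiles lay on chromosome 2 at 239703001 to 239704000 (99.6% over passages 27 and 28), 7260001 to 7261000 (99.4%) and 183473001 to 183474000 (99.0%), on chromosome 19 at 53832001 to 53833000 (99.0%) and on chromosome 4 at 3511001 to 3512000 (98.9%). None of these 5 passed the test for a change with all 8 libraries at 10 reads. Their choice by a high level at passages 27 and 28 left no room for a large fall, so this is no evidence of stability. At 5 reads the tile on chromosome 4 passed with a fitted change of -2.93 points (adjusted p = 0.0324, limma's moderated dispersion).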

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

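Of the tests in this part, those of passage order, of bisulfite conversion and of chromosome X were chosen after the results were seen. For depth, thinned reads for the tiles were fixed before, and thinned reads for the library means were added later.

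CpGs of chromosome X, which lay outside the autosomal comparison, lost more methylation than the autosomes. Over 2293 CpGs the mean went from 64.4% ± 1.22 (SD, n = 3) at passages 6 to 8 to 46.7% at passages 27 and 28, a change of -17.7 points. Among CpGs that started at 80% or more, the change was -14.6 points on chromosome X (1178 CpGs) and -12.0 points on autosomes (67097 CpGs). The slope of chromosome X minus that of the autosomes in this class was -0.129 ± 0.0187 points per passage (SE, n = 8; exact permutation p = 0.0044).

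For the fall of methylation with passage, technical explanations were weighed. Incomplete bisulfite conversion in early libraries would raise unmethylated tiles there by more points than highly methylated ones, which hold few unmethylated reads. Tiles starting at 80% or more moved by -13.3 points. Tiles under 1% on average moved by -0.0563 points, from 0.191 to 0.135%, and fell with passage (rho = -0.976, exact permutation p = 0.0004). Choosing them by their mean over all libraries limited how far they could move. By level at passages 6 to 8 alone, 12478 of the 22626 tiles lay under 10%, with a mean of 0.784%. Incomplete conversion large enough for the -13.3 points would not leave so many tiles so low. With reads thinned to equal coverage, the slope of the mean was -0.452 points per passage. Thinning the same CpGs leaves their expected mean unchanged, so this slope cannot decide whether depth matters. Calls of tiles do depend on depth, and with thinned reads 5319 of 11120 tested tiles lost methylation (47.8%), so unequal depth is not needed for these calls. Of 100 orders of the passage numbers, 1, the real one, gave as many called tiles (5610). The highest other order gave 3563 and correlated with the real order at r = 0.832. A chance order is thus unlikely, but 100 of the 40320 orders cannot exclude it. Nor can shuffling separate passage from anything else that follows the order of the libraries. A biological loss in the absence of both enzymes remains a hypothesis consistent with these tests, but no library of cells with the enzymes was analysed here, so loss from culture alone stays open.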

How the results depend on the processing

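Results for passages 6 to 17, for tiles starting at 80% or more, for limits on reads of each state and dispersion, and with thinned library means were chosen after seeing the data. The slope of the mean stayed negative with an exact permutation p under 0.05 in every alternative run, between -0.385 (20 reads) and -0.458 (without passage 27). So did the high class, and the low class stayed positive. The slope of the intermediate class turned to 0.0627 at 5 reads and 0.0779 at 20 reads; the cause was not tested.

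Tiles losing methylation numbered 26588 of 78387 tested at 5 reads, 161 of 701 at 20 reads, 1429 of 3552 with at least 5 CpGs, and 2159 over passages 6 to 17. The first 3 counts do not only follow the number of tiles tested, since the shares were 33.9%, 22.97% and 40.2%, against 47.6% in the main fit. Gains numbered 130 at 5 reads, 0 at 20 reads, 6 with at least 5 CpGs, 10 with limma on logit levels, 33 without a minimum change and 7 at 20 points. With no gain at 20 reads, 363 tiles had an unadjusted p under 0.05 in either direction, by the fit with limma's moderated dispersion. The share losing methylation was 22.97% at 20 reads, 20.6% with limma on logit levels, 18.8% over passages 6 to 17, 27.2% without the minimum of reads and 28.9% also without the dispersion floor; the last pair and the limma fit also tested near-unmethylated tiles.

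The density difference was -0.00818 among tiles starting at 60% or more. Among those starting at 80% or more it was -0.0358 (exact permutation p = 0.418), 0.179 at 5 reads (p = 0.00149, same test) and 0.107 at 20 reads (p = 0.000397, same test). So it passed the test at both other coverage minimums and not at 10 reads. On omission of single libraries it was -0.0502 to 0.00995 (highest without passage 27), and the cause was not tested. Kept tiles made up 61.8% at a level of 70%, 48.5% at 90%, 57.0% at 5 reads and 68.6% at 20 reads. For named tiles, 233 of the values under alternatives stayed on their side of the threshold, 27 lost it and 1 passed it newly. The last was the best kept chromosome 4 tile at 5 reads, at -2.93 points against 1.51 in the main fit. Another 2 reversed, both over passages 6 to 17, the chromosome 4 rise at -4.51 points and the chromosome 16 rise at -9.71. Reversals were counted for called tiles only. Best kept tiles also changed sign, such as chromosome 2 at 7260001, at -0.337 points without passage 27. Many changes of 20 points at intermediate levels would be missed, since 34 to 36% of them were recovered in simulated tiles of 1 common dispersion. Depth was not varied there, so its part in this was not tested. Alternatives for promoters and gene lists were not run, for want of an hg19 annotation. No paired analysis was possible because each passage has 1 library.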

Other observations

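Tests of chromosome ends and chromosomes and of reads in a single late library were chosen after the result was seen. So were those of random placement, of copy number and of loss of unmethylated copies. Predictions for a steady pace, allele loss and conversion in late libraries were written before the results of those tests were seen. None of the tests in this part belonged to the design fixed beforehand.

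Highly methylated tiles near chromosome ends lost more methylation than those farther in. Tiles starting at 80% or more within 5 Mb of the first or last CpG of a chromosome (1666) went from 89.8% ± 0.255 (SD, n = 3) to 72.8%, and the other 2636 from 90.8% ± 0.0529 (SD, n = 3) to 79.9%. The difference of slopes was -0.296 ± 0.0347 points per passage (SE, n = 8; exact permutation p = 0.000223, adjusted p = 0.000558). With tiles matched on CpG density and starting level it was -0.210 ± 0.0252 (SE, n = 8; exact permutation p = 0.000322). By chromosome, the change of such tiles was largest on chromosome 21 (-19.3 ± 2.22 points, SE over 95 tiles) and smallest on chromosome 4 (-8.23 ± 0.834 points, SE over 256 tiles), where tiles are not independent replicates. Of the 1319 tiles that started between 40 and 60%, 211 were still in that range at passages 27 and 28, and 779 were under 20%.

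A small set of tiles fell by at least 70 points between passages 17 and 27. Of 3463 tiles at 80% or more at passage 17, 23 (0.664%, Wilson interval 0.443 to 0.9947%) lay at least 70 points lower at passage 27, against 2 of 4421 (0.0452%, 0.0124 to 0.165%) between passages 6 and 17. The tiles' own trends over passages 6 to 17 predicted 0 such falls, but this test cannot decide on loss at a steady pace. Tiles still at 80% or more at passage 17 could not have had a trend steep enough to predict a fall of 70 points. The mean change of these 3463 tiles to passage 27 was -8.44 points. From passage 6 to 17, the 4421 tiles at 80% or more at passage 6 changed by a mean of -5.62 points. Shallow reads in a single late library are argued against: 100% of the 23 lay at least 35 points below passage 17 at passage 28 (Wilson interval from 85.7%), and 16 at least 70 points below. Among the 23, the smallest fall from passage 17 to 28 was 43.2 points. Growth of a subclone that had already lost these tiles may account for the pattern and was not tested; tiles between 45 and 55% at passages 27 and 28, where loss of 1 allele in a clonal population would put them, numbered 0.758 times the mean of the neighbouring bins.

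Rises were concentrated on 1 stretch of chromosome 1. Of the 21 tiles that gained methylation, 9 lay between 2978001 and 3333000 (hg19), in a window of 500 kb with 48 tested tiles, of which 15 lost methylation. At a minimum of 5 reads, 35 of 130 gaining tiles lay there. Weakly methylated CpGs of the stretch (427, with at least 5 reads) had 2.31% at passage 17, 16.6% at passage 27 and 20.9% at passage 28, while 6479 such CpGs in the rest of the first 10 Mb had 0.736%, 0.528% and 0.481%. Another 4 gains lay on chromosome 16 between 839001 and 1081000.

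For this stretch, 10000 random placements of the rises put at most 4 into any window (permutation p = 0.0001, the smallest they can give), although neighbouring tiles are not independent. Poorer conversion in the late libraries is argued against by the change of -1.36 points in the surrounding CpGs. Copy number stays open: the stretch's share of nearby reads at passages 27 and 28 was 0.926 of that at passages 6 to 17, outside the range of those 6 libraries (0.970 to 1.04), and of 1733 autosomal windows of 355000 bases 1 had a ratio as low. A first bound of 10% would have counted this ratio as no change and was replaced after the ratio was seen. Loss of unmethylated copies alone could raise the level by a factor of at most 1.08, against the 5.78 measured, so a gain of methylation in part of the cells, with or without a change in copy number, is a candidate explanation that these data cannot settle.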
